A study of Homo sapiens with 2 samples.

How the data were processed

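RNA was measured by sequencing in 2 libraries of HGC-27 cells, a human gastric carcinoma line, collected 48 hours after transfection (with the reagent INTERFERin) with either an empty expression vector or the same vector carrying the long non-coding RNA lncPSCA. Total RNA was extracted with Trizol, per the labels' protocols. The authors deposited 1 table of read counts per Ensembl gene, with 1 column for each library and 63677 genes. The values are raw counts: whole numbers with different totals in each column. TopHat2, HTSeq and the genome build hg19 are named in the submitters' processing notes, without versions or settings. The annotation release, the strand setting of the counting, any read filter, the library kit and the read length are not given in the sources used here. Because the strand setting is unknown, reads of a gene and of a gene overlapping it on the opposite strand cannot be told apart. Genes with near-identical copies share reads in a way that depends on how multiply mapped reads were treated, which is also not given.

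The control library held 21552098 counts and the lncPSCA library 23016646 counts. All rows of the table name a gene, so no row was removed from the totals. Gene symbols were assigned through a table of Ensembl gene identifiers and symbols, which matched 52181 identifiers (81.9%). Unmatched identifiers held 1.23% of the control counts and 1.30% of the lncPSCA counts, and they stayed in the totals and in the counts of genes. No annotation of the authors' build was used, so no coordinates are given. Whether genes overlap, and transcript lengths and GC content, were taken from GENCODE release 29, an annotation of a different build (GRCh38), matched by gene identifier.

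Library sizes were scaled by the trimmed mean of M values (TMM, edgeR 4.0.16), with factors of 0.979 for control and 1.02 for lncPSCA. Counts-per-million values (CPM) were computed from these scaled sizes. The log2 ratio of lncPSCA over control was computed on counts plus a pseudocount of 1 scaled to library size, which understates the ratio of genes with few reads. Folds are ratios of CPM without the pseudocount. Each fold has an exact 95% counting interval (Clopper-Pearson, on the share of a gene's reads that came from 1 of the libraries). These intervals cover counting error only and no spread between cultures, since each group has 1 library. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for counting error. Where the control library had no reads, the fold was computed against 3 counts, the limit that a count of 0 allows, which corresponds to 0.142 CPM in the control library.

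Each group has 1 library, so no test between the groups was possible, no p-value is given, and no difference has a replicate check. Genes were instead described by a fixed size rule: a mean of at least 1 CPM over the 2 libraries, at least a 2-fold difference on the pseudocount scale, and a counting interval lying wholly beyond 1.5-fold. "Higher" and "lower" below refer to the lncPSCA library relative to control and, for single genes, to this rule. In all, 15440 genes reached the CPM minimum, 499 of them without a matched symbol. On simulated libraries with counting noise alone and 200 changed genes among 15448, the rule found 35.0% of genes changed 2-fold, 95.0% of those changed 3-fold, 97.5% of those changed 4-fold, none of the 40 genes changed 1.5-fold, and none of the 15248 unchanged genes. The spread between replicate cultures was not measured. In simulations with no changed gene, an assumed coefficient of variation between replicates of 0.1 gave 5 genes meeting the rule, 0.2 gave 263, and 0.4 gave 3351.

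The following choices were made before the data were examined: the size rule, 30 gene lists with 760 entries, the alternatives, and the rule for the genes to be named. Named genes included PSCA, DDX5 and DDX17; among genes with a symbol that met the size rule, the 12 per direction with a mean of at least 5 CPM and the largest ratio, and the 8 per direction with the largest CPM difference; and up to 4 members of each list that met the size rule, or its 2 most abundant members where none did. Genes named outside this rule are given as chosen after their values were seen. The same holds, without being repeated there, for EEF1A1 and the PSCA neighbours ADGRB1, ARC, THEM6 and TOP1MT. It also holds for IFITM2, IRF7, HERC5 and EPSTI1 of the interferon list. Of each list with at least 3 measured members, the median log2 ratio was placed among 10000 random lists of the same size, drawn from measured genes in 20 bins of mean expression. Transcript length was not matched. The counting interval of a median came from 500 Poisson redraws of both libraries. These percentiles describe 2 libraries and are not tests of the transfection, since genes are not independent replicates.

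Alternatives were DESeq2 1.42.0 size factors, total counts and upper-quartile scaling; no CPM minimum and a minimum of 5 CPM; pseudocounts of 0.5 and 5; the deeper library thinned to 21552098 counts; fold thresholds of 1.5 and 3; no condition on the interval; and intervals widened by assumed coefficients of variation of 0.2 and 0.4. After seeing the data, 3 more were added: TMM without PSCA, JRK and the interferon list, and log2 ratios centred by running medians along mean expression, or along the GC content and length of the longest transcript (known for 97.1% of measured genes). Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.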

Results

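The transcriptomes of 2 cultures of HGC-27 cells, a human gastric carcinoma line, were compared 48 hours after transfection: 1 control culture with the empty vector and 1 culture with the vector carrying lncPSCA. The comparison asks which transcripts differ in abundance when this long non-coding RNA is overexpressed. The control library held 21552098 counts over 24792 genes with at least 1 read, and the lncPSCA library held 23016646 counts over 25900 genes. The 10 most abundant genes of each library took 4.76% and 5.21% of its counts, and EEF1A1, a translation elongation factor, led both. There was 1 library per group, so every difference below is between 2 libraries, has no replicate check and carries a counting interval only.

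No row of the table is named lncPSCA, so the overexpressed RNA itself was not matched. Among measured genes with a symbol, the largest ratio belonged to PSCA (ENSG00000167653, chromosome 8), which encodes a cell-surface antigen of the Ly6 family. PSCA had 22 reads in the control library and 28699 in the lncPSCA library, or 1.04 and 1221 CPM. This is a 1171-fold difference (95% counting interval 773 to 1868). The gene JRK (ENSG00000234616), which overlaps PSCA on the opposite strand in GENCODE release 29, had 729 and 7356 reads. JRK was 9.06-fold higher (8.39 to 9.79). The strand setting of the counting is not known, so it is open how reads over the overlap were assigned to each gene. Other measured genes of the region had far smaller ratios. ADGRB1 was at 2.05-fold (1.46 to 2.91) and ARC at 1.59-fold (0.961 to 2.68), and neither met the rule. THEM6 was at 49.7 CPM in control and 51.6 CPM in lncPSCA, a fold of 1.04 (0.955 to 1.13), and TOP1MT had a fold of 0.998 (0.922 to 1.08). LY6E, a Ly6 family gene on the same chromosome, was 2.01-fold higher (1.94 to 2.08). Whether this difference was tied to the region was not tested. Of the 7 measured members of the list of Ly6 genes and neighbours of PSCA, PSCA, JRK and LY6E were higher and 4 met the rule in neither direction, and all 7 had a log2 ratio above 0. LY6E fell short of the rule under upper-quartile scaling and with an assumed coefficient of variation of 0.2. Of the 3 gastric and intestinal markers that were measured, PSCA was the only one to meet the rule.

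Interferon-stimulated genes were far more abundant in the lncPSCA library. Of 46 measured interferon-stimulated genes, 45 were higher, none was lower and 1 (IRF7, 47 and 45 reads) met the rule in neither direction. Their median log2 ratio was 4.44 (counting interval 4.33 to 4.62), a 21.7-fold difference, above the medians of all 10000 random lists, whose middle 95% ran from -0.19 to 0.04. Together the 46 genes took 0.086% of all counts in the control library and 1.29% in the lncPSCA library. The smallest log2 ratio among the 45 was 1.43, for IFITM2, and the largest was 8.33, for MX2. The 2 members that were not measured were HERC5, with 0 and 12 reads, and EPSTI1, with no reads in either library.

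MX2, a dynamin-like GTPase that restricts viruses, had 20 and 7501 reads and was 337-fold higher (218 to 551). OAS2 and OAS1, which make the second messenger that activates RNase L, were 177-fold (132 to 242) and 55.2-fold (44.4 to 69.6) higher, and OAS3 was 45.2-fold higher (41.1 to 49.8). RSAD2, which encodes viperin, was 104-fold higher (73.9 to 153). XAF1, a pro-apoptotic interferon target, had no reads in control and 225 in lncPSCA, at least 67.3-fold higher against the limit of 3 control counts. TRIM22 was 93.6-fold higher (47.3 to 217), IFI27 51.5-fold (44.1 to 60.5), DDX60 51.8-fold (40.3 to 67.8) and OASL 51.4-fold (41.6 to 64.2). BATF2, an interferon-induced transcription factor that was not on the list, was 78.8-fold higher (46.8 to 145). CXCL10, a chemokine that attracts T cells, had only 2 control reads against 337, a ratio of 151 (41.5 to 1254).

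**Figure D1:**
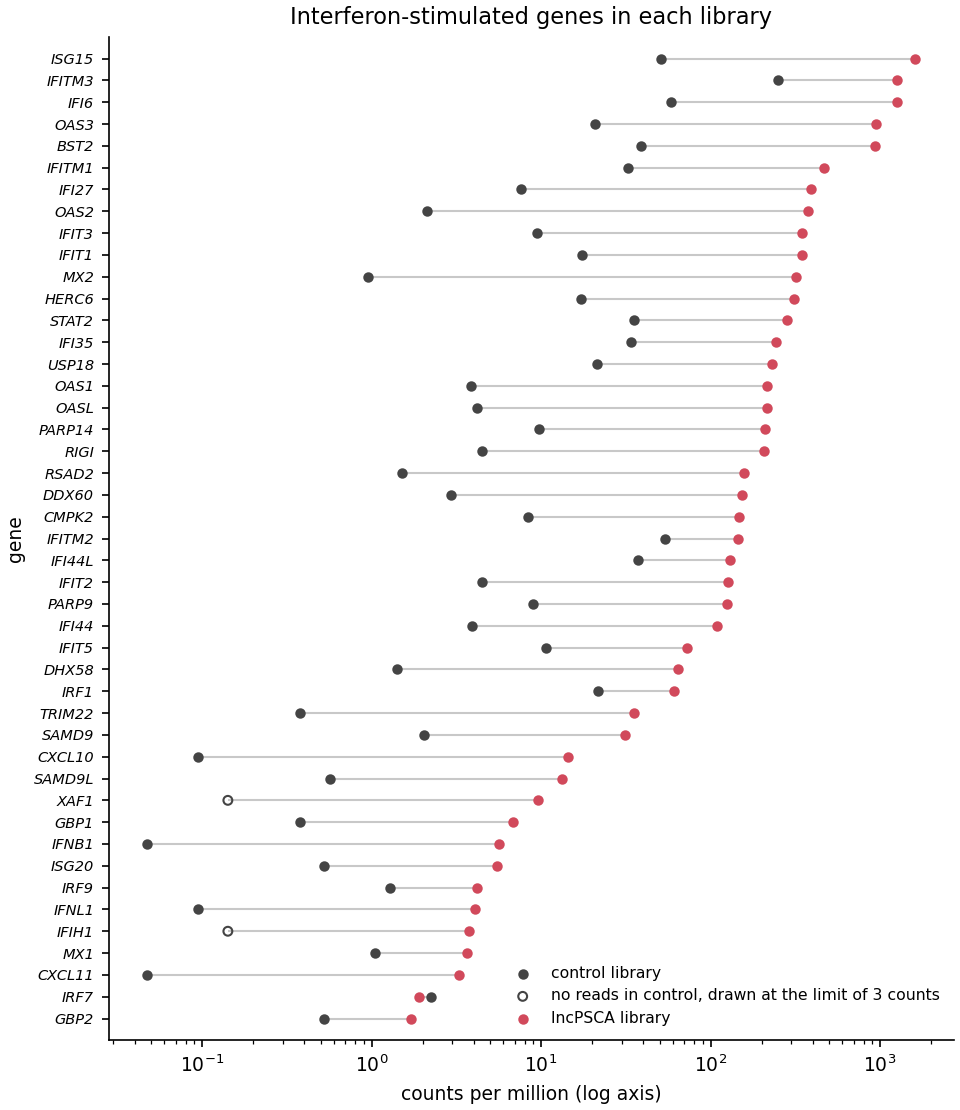
Abundance of 45 of the 46 measured interferon-stimulated genes in the control library (dark points) and the lncPSCA library (red points), in CPM on a log axis, 1 library each; open circles are genes without control reads, drawn at the limit of 3 counts. The red point lies to the right of the control point for 44 genes, and IRF7 is the exception.

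Among genes with a symbol that met the size rule, the largest gains in CPM included those of ISG15, PSCA, IFI6, DDIT4, IFITM3, OAS3 and BST2. ISG15, a ubiquitin-like modifier, went from 51.0 to 1615 CPM, a fold of 31.6 (29.8 to 33.6). IFI6 went from 58.1 to 1252 CPM, and BST2, which tethers budding virions and is known as tetherin, from 39.1 to 931 CPM. IFITM3 was 5.03-fold higher (4.88 to 5.18). RIGI, a cytosolic sensor of viral RNA, was 46.1-fold higher (37.7 to 57.1). Transcripts of the interferons themselves were also present: IFNB1 had 1 read in control and 132 in lncPSCA, a ratio of 118 (20.9 to 4714), and IFNL1 had 2 and 96 reads, a ratio of 43.1 (11.6 to 361). These 2 genes belong to the interferon list and were named after their values were seen.

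Over all 15440 measured genes, 467 were higher and 92 were lower in the lncPSCA library, so 83.5% of the genes that met the size rule were higher. The 45 interferon-stimulated genes were among the 467, which left 422 others. The list does not hold every interferon-induced gene, and BATF2 was among these others. At a difference of at least 8-fold, 67 genes were higher, 35 of them from the interferon list, and 2 were lower. The counts depend on a spread between cultures that was not measured: with an assumed coefficient of variation of 0.2 they were 207 higher and 26 lower, and with 0.4 they were 103 and 5. Of the 45 interferon-stimulated genes, 44 still met the rule with 0.2 and 39 with 0.4.

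**Figure D2:**
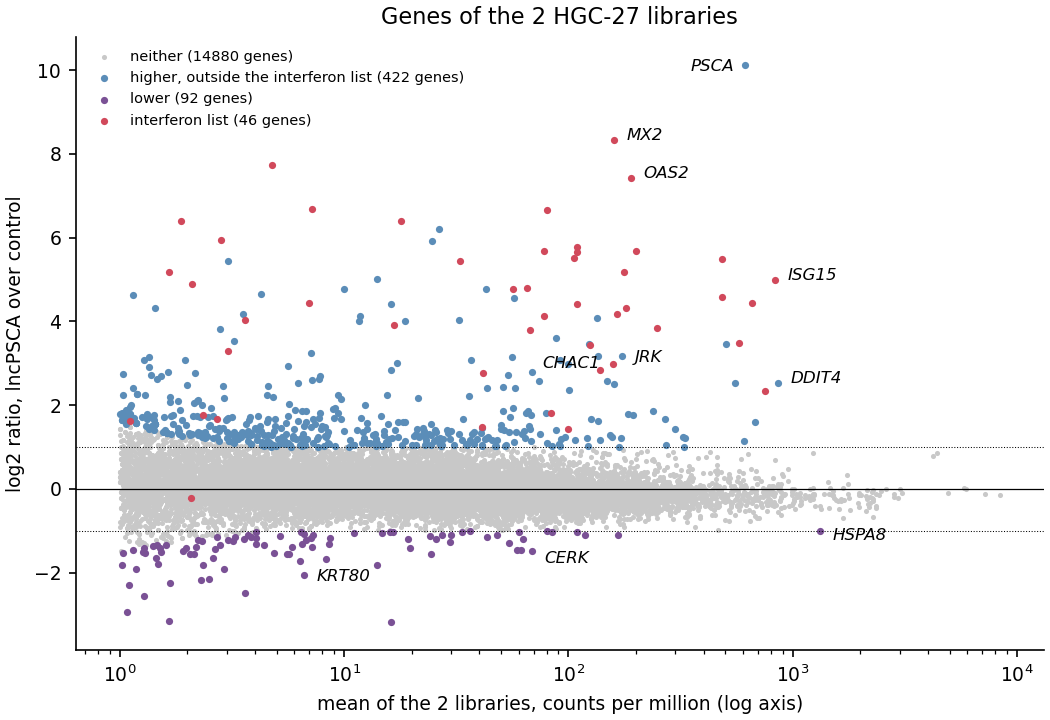
Log2 ratio of lncPSCA over control (vertical axis) against the mean of the 2 libraries in CPM (horizontal, log axis) for the 15440 measured genes; dotted lines mark 2-fold, and colours mark the interferon list and the genes that met the size rule. PSCA stands at a log2 ratio of 10.13, and 45 of the 46 interferon-stimulated genes lie above the upper dotted line.

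Some genes of the integrated stress response and unfolded protein response were also higher. Of 24 measured members, 5 were higher, none was lower and 19 met the rule in neither direction. The list median was 0.49 (0.44 to 0.51), above all 10000 random lists. CHAC1, which degrades glutathione, was 6.94-fold higher (6.22 to 7.76). DDIT4, an inhibitor of mTORC1 signalling, went from 253 to 1469 CPM, a fold of 5.81 (5.65 to 5.98). SESN2, a leucine sensor that is also a p53 target, was 3.51-fold higher (3.24 to 3.81), SLC7A11, the cystine transporter, 2.58-fold (2.37 to 2.82), and the transcription factor ATF3 2.08-fold (1.95 to 2.23). The chaperone HSPA5, the classical marker of the unfolded protein response proper, had a log2 ratio of -0.19; it was named after its value was seen. With an assumed coefficient of variation of 0.2, 3 of the 5 members met the rule.

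Most p53 target genes differed little between the libraries. Of 35 measured p53 target genes, 3 were higher, none was lower and 32 met the rule in neither direction. The higher genes were SESN2, CDKN1A, the cell cycle inhibitor p21, at 2.06-fold (1.80 to 2.36), and GDF15, a stress-induced cytokine, at 2.03-fold (1.79 to 2.30). The list median was a log2 ratio of 0.12 (0.05 to 0.17), at the 96.7th percentile of random lists, inside their middle 95% of -0.17 to 0.13. Over the scalings tried, between 2 and 5 members were higher, with an assumed coefficient of variation of 0.2 it was 1, and with 0.4 it was 0. DDX5, an RNA helicase and p53 coactivator, fell short of the rule at 0.704-fold (0.684 to 0.724), with 522 CPM in control and 367 CPM in lncPSCA. Its paralog DDX17 was at 270 and 259 CPM, a fold of 0.957 (0.923 to 0.993), and its log2 ratio changed sign when centred along mean expression (0.08). Of 27 measured DEAD-box helicases none met the rule; the list median was -0.24, within the random range, and DDX39A had a log2 ratio of -0.40.

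Among inflammatory NF-kB targets, 3 of 11 measured members were higher: TNF with 5 and 43 reads (7.72-fold, lower bound 3.06), the adhesion molecule VCAM1 at 3.63-fold (3.28 to 4.03) and the NF-kB inhibitor TNFAIP3 at 3.55-fold (2.80 to 4.54). The list median of 0.64 lay above the random range, which ended at 0.34. Of 23 immediate early genes, KLF2 (2.76-fold, 2.39 to 3.19) and ATF3 were higher, and the median was 0.29. In the hypoxia and glycolysis list, CA9, a hypoxia-induced carbonic anhydrase, had 2 and 141 reads, a ratio of 63.3 (17.2 to 528), and the glycolytic regulator PFKFB4 was 2.85-fold higher (2.23 to 3.67). The other 27 of its 29 members met the rule in neither direction, and the median was 0.02, which changed sign under upper-quartile scaling (-0.01). Both measured metallothioneins, MT2A (152 and 248 CPM) and MT1X, fell short of the rule.

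Genes that were lower had smaller ratios. Among genes with a symbol and a mean of at least 5 CPM, the largest were those of the keratin gene KRT80, 4.20-fold lower (3.14 to 5.68), CAPN12, 3.54-fold (2.93 to 4.30), the neuropeptide gene ADCYAP1, 3.34-fold (2.53 to 4.46), and PRR11-AS1, 3.20-fold (2.52 to 4.10). UPK3B (2.98-fold), FHL1 (2.97-fold), the mitochondrial import gene TIMM21 (2.96-fold), the ceramide kinase gene CERK (2.78-fold), H3P6 (2.74-fold) and AP1M2 (2.64-fold) were also lower; AP1M2 fell short of the rule with an assumed coefficient of variation of 0.2. CYP1A1, the xenobiotic-metabolising enzyme, was 2.75-fold lower (2.53 to 2.99), and OSGIN1, an oxidative stress response gene, 2.67-fold (2.30 to 3.11). H3P6 is a histone pseudogene that shares sequence with its parent gene, and PRR11-AS1 is an antisense gene counted with an unknown strand setting, so both values are uncertain. The antisense gene ENSG00000251131, which has no symbol and was named after its values were seen, had a larger ratio, with 615 reads in control and 74 in lncPSCA. Among genes with a symbol that met the size rule, the largest losses in CPM also included HSPA8, DANCR, TRIM16L, LSM3 and MAPKAP1, all of which fell short of the rule under either centring and with an assumed coefficient of variation of 0.2. All of these but DANCR also fell short under total-count scaling. DANCR, a non-coding snoRNA host gene, was 2.16-fold lower (2.05 to 2.26), LSM3, a splicing factor, 2.04-fold (1.91 to 2.19), MAPKAP1 2.02-fold (1.89 to 2.17), and TRIM16L, which has a near-identical copy, 2.04-fold (1.92 to 2.16).

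Some heat shock genes were lower: of 14 measured members, 3 were lower and none was higher, and the median of -0.34 (-0.42 to -0.24) lay at the 0.3rd percentile of random lists. HSPA8, the constitutive HSC70 chaperone, went from 1764 to 873 CPM, 2.02-fold lower (1.99 to 2.06). The stress-inducible and near-identical genes HSPA1B and HSPA1A were 2.31-fold (2.13 to 2.51) and 2.05-fold (1.89 to 2.22) lower, and their split of shared reads is uncertain. The 3 genes lie close to the 2-fold limit: 1 met the rule under total-count scaling and under either centring, and none did with an assumed coefficient of variation of 0.2.

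Lists of growth and housekeeping genes shifted by small amounts without genes that met the rule. The 70 cytosolic ribosomal protein genes had a median log2 ratio of -0.22, and 1 of them lay above 0. RPS2 was at -0.13 and RPLP0 at -0.11, and both changed sign under either centring (0.02 and 0.04 along mean expression). The 39 nuclear-encoded respiratory chain genes had a median of -0.28 (ATP5F1B -0.22, ATP5F1A -0.20), below the random range, which started at -0.22. Ribosome biogenesis genes had a median of -0.20 (NPM1 -0.67, NCL -0.27) and histone genes one of -0.18 (H2BC12 -0.14, H1-2 -0.41), both within the random range. Centring along mean expression brought the ribosomal median to -0.07 and the respiratory chain median to -0.16. Of 13 mitochondrially encoded mRNAs, 11 had a log2 ratio above 0 and none met the rule, with a median of 0.21. MT-CO1 was at 0.79 and MT-CO2 at 0.12, and the 2 members below 0 were MT-ND3 (-0.98, lower under upper-quartile scaling) and MT-ATP8 (-0.27), named after their values were seen. Under either centring, 1 member of this list was higher and none was lower. Mitochondrial mRNAs made up 1.05% of control and 1.47% of lncPSCA counts, and mitochondrial ribosomal RNA 0.364% and 0.656%.

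Across the genome, the ratio of the libraries also followed mean expression and transcript length. Across the measured genes, the Spearman correlation of log2 ratio with mean CPM was -0.226. Its median was 0.148 in the lowest quartile of mean CPM and -0.133 in the highest. The correlation with transcript length was 0.236. When genes were split into 10 groups by length, the 1494 with the longest transcripts (median 9242 bases) had a median log2 ratio of 0.25, with 101 genes higher and 1 lower. In the group second from the bottom (median 1311 bases) it was -0.15, with 35 higher and 10 lower. The figures of these length groups leave out PSCA, JRK and the interferon list. Of 30 mitotic genes, CENPF was higher (2.64-fold, 2.41 to 2.90) and none was lower, with a median of -0.22 within the random range. Of 29 DNA repair genes, BRCA2 (3.24-fold, lower bound 2.63) and BRCA1 (2.10-fold, 1.89 to 2.33) were higher, with a median of 0.29; their longest transcripts measure 11986 and 7270 bases, and that of CENPF 10307 bases. Across genes within each list, the Spearman correlation of length with log2 ratio was 0.63 for mitosis and 0.74 for repair, where genes are not independent replicates. Of the other 7 lists looked at, it was 0.51 for ribosome biogenesis, 0.49 for cholesterol synthesis, 0.44 for DNA replication, 0.215 for DEAD-box helicases, 0.05 for the respiratory chain, 0.01 for the interferon list and -0.06 for p53 targets. Centring along GC content and length brought the repair median to 0.16. CENPF and BRCA2 still met the rule after this centring, with log2 ratios of 1.05 and 1.24, and BRCA1 fell short of it at 0.85, as it did with an assumed coefficient of variation of 0.2.

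**Figure D3:**
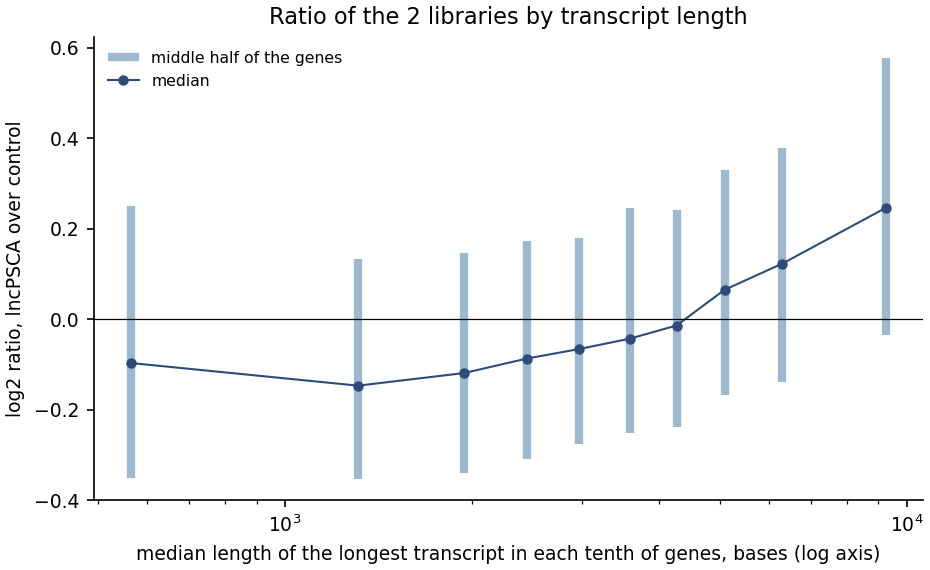
Median log2 ratio of lncPSCA over control (points) and the interquartile range of genes (bars) in 10 equal groups of 14945 genes ordered by the length of their longest transcript in bases (log axis), without PSCA, JRK and the interferon list. The median runs from -0.10 in the shortest group and -0.15 in the second to 0.25 in the longest.

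In the remaining lists few or no genes met the rule. None of 24 apoptosis regulators did (median -0.06; CYCS 650 and 384 CPM, MCL1 214 and 178 CPM), and neither did any of 25 DNA replication genes (median 0.02; MCM7 797 and 831 CPM, MCM4 372 and 347 CPM, its log2 ratio of opposite sign when centred along mean expression), 24 cholesterol biosynthesis genes (median 0.06; SQLE 818 and 630 CPM, SREBF2 314 and 348 CPM), 18 TGF-beta targets (median -0.19; ID3 345 and 450 CPM, ID1 232 and 237 CPM) or 22 YAP/TAZ targets (median -0.24; IGFBP3 370 and 310 CPM, GADD45A 99.7 and 113 CPM). The YAP/TAZ median lay below the random range, which started at -0.21, and the cholesterol and replication medians lay above theirs, which ended at 0.04 and 0.02. The means of the apoptosis list (0.002), the replication list (-0.03) and the epithelial list (0.04) had the opposite sign to their medians, and all 3 medians changed sign under 1 scaling; without members under 5 CPM the epithelial median was 0.76. Among 16 Wnt targets, RNF43 (3.10-fold, 2.34 to 4.16) and TNFRSF19 (2.24-fold, 1.51 to 3.40) were higher and BMP4 was lower (2.31-fold, 2.04 to 2.63), with a median of 0.10. CLDN7, a tight junction gene, was the only one of 12 epithelial genes to meet the rule (2.08-fold, 1.54 to 2.83; list median -0.02), and FN1, fibronectin, the only one of 22 mesenchymal genes (2.35-fold, 2.13 to 2.59; list median 0.15). The mesenchymal median lay above its random range, which ended at 0.06. Of 13 long non-coding RNAs, KCNQ1OT1 (2.78-fold, 2.19 to 3.56) and NEAT1 (2.24-fold, 2.12 to 2.37) were higher and DANCR was lower, with a median of 0.11. Several of these calls were lost under other settings: TNFRSF19 under upper-quartile scaling, thinning and centring along mean expression, CLDN7 under that centring (where 1 other epithelial gene was lower), DANCR under either centring, and FN1 and NEAT1 when centred along GC content and length. With an assumed coefficient of variation of 0.2, RNF43 and KCNQ1OT1 alone among these 8 genes still met the rule.

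Few markers of other cell types met the rule. None of 7 measured blood and immune genes met the rule (median 0.33, within the random range, and -0.14 without members under 5 CPM), with HBA2 at 56.6 and 51.4 CPM and HBA1 at 19.3 and 14.9 CPM; reads of these near-identical genes cannot be assigned with certainty. Of 8 fibroblast and endothelial genes, PDGFRB was higher (2.08-fold, 1.53 to 2.88; 2.80 and 5.83 CPM). The median of this list, 0.25, lay above its random range, which ended at 0.225. PDGFRB fell short of the rule under upper-quartile scaling, under either centring and with an assumed coefficient of variation of 0.2. Of the liver and lung markers only NKX2-1 was measured, at 2.27 and 2.34 CPM. Of the 28 lists with at least 3 measured members, 11 had a median above the random range, 4 below it and 13 within it. The random lists were not matched on transcript length, which the ratio also followed, so lists of long or short genes can leave the range for that reason.

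**Figure D4:**
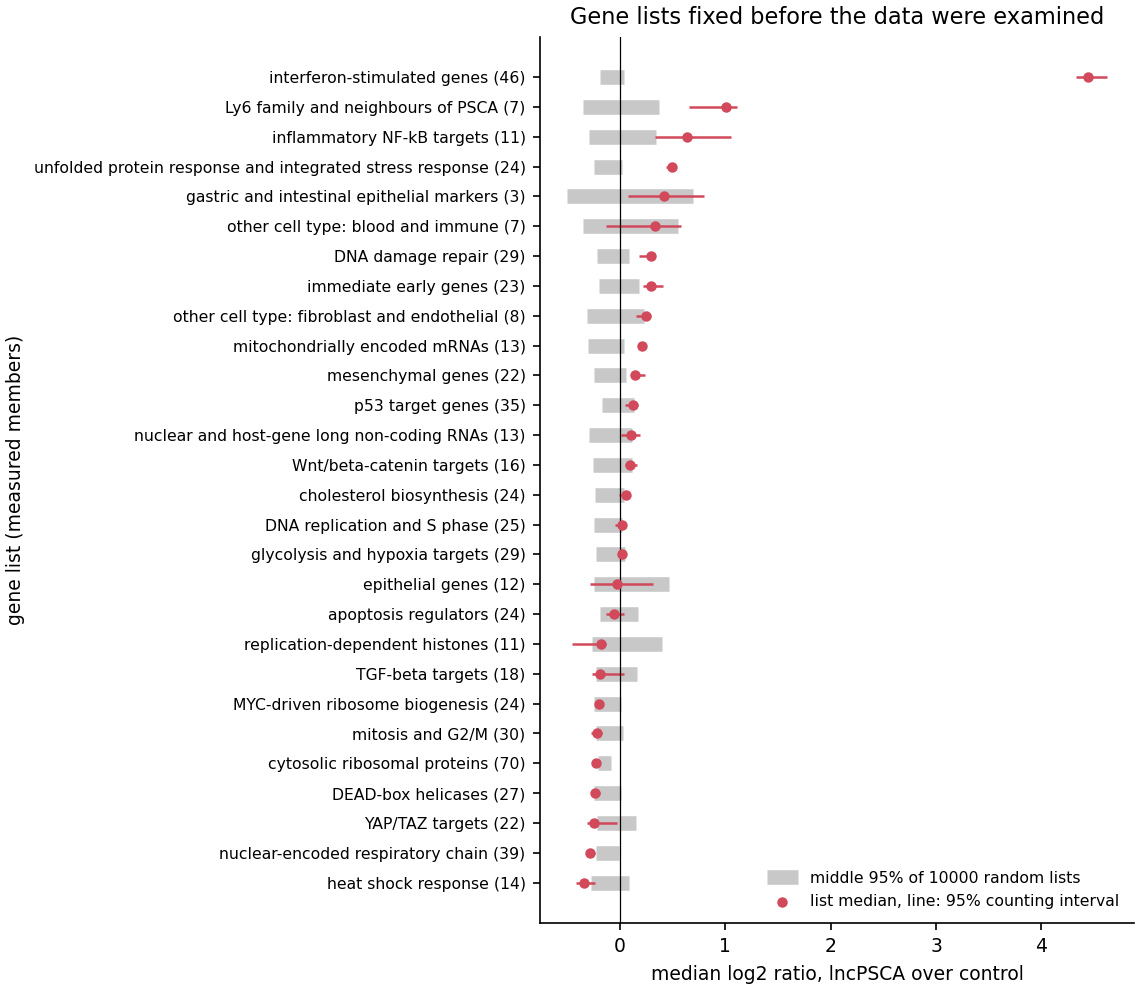
Median log2 ratio of lncPSCA over control for 28 gene lists (points) with the 95% counting interval (lines) and the middle 95% of the medians of 10000 random lists matched on mean expression (grey bars); the number of measured members is in brackets. The interferon list stands at 4.44, and the next list, of Ly6 genes and neighbours of PSCA, at 1.01. That list includes PSCA and JRK themselves, and its median over 7 measured members is the value of LY6E.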

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

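The choice of scaling (DESeq2 size factors, total counts, upper quartile, TMM without PSCA, JRK and the interferon list), the pseudocount, the thinning of the deeper library and both centrings kept the counts of higher and lower genes within 1.5 times of 467 and 92. The centrings exchanged genes: along mean expression 401 were higher and 134 lower, sharing 376 and 82 with those counts, and along GC content and length 438 were higher and 89 lower, sharing 380 and 69. The counts moved further with the thresholds: a minimum of 5 CPM gave 284 higher and 46 lower genes, a fold threshold of 3 gave 197 and 20, an assumed coefficient of variation of 0.2 gave 207 and 26, and one of 0.4 gave 103 and 5, stricter rules that remove genes by construction. Lower genes numbered 150 without the CPM minimum, 273 with a fold threshold of 1.5 and 145 without a condition on the interval; each of these settings admits more genes by construction. The median of the p53 targets was 0.184 with total counts only, against 0.123, a scaling that shifts every gene alike, and that of the interferon-stimulated genes was 4.15 with a pseudocount of 5, against 4.44, where a larger pseudocount lowers the ratio of genes with few control reads by construction. None of the named genes that met the rule changed sign under the settings tried. For the other lists, 239 recomputed medians stayed within their counting interval and 47 did not, and for named genes other than PSCA 893 values stayed within it and 111 did not. At this depth a count of 0 allows up to 0.142 CPM in the control library and 0.128 CPM in the lncPSCA library. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The centrings and the reduced TMM were chosen after seeing the data.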

Other observations

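All gene lists and tests in this part were chosen after the data were seen. Of 18 measured genes for antigen presentation, 10 were higher and none was lower, with a median log2 ratio of 1.41. NLRC5, the transactivator of MHC class I genes, was 8.44-fold higher (95% counting interval 7.62 to 9.37), the peptide transporter gene TAP1 5.71-fold (5.35 to 6.11), the immunoproteasome gene PSMB9 5.33-fold (4.78 to 5.95), HLA-F 4.55-fold (3.84 to 5.42) and CD274, which encodes PD-L1, 4.33-fold with 17 and 82 reads (2.55 to 7.79). Of 13 complement and apolipoprotein L genes, 9 were higher and none was lower, among them APOL6 (16.5-fold, 12.2 to 22.8) and C4A (7.21-fold, 5.73 to 9.17), whose reads are shared with C4B. Of 11 nucleic acid sensors and adaptors, 6 were higher, among them EIF2AK2, the kinase PKR, at 3.60-fold (3.44 to 3.78), TLR3 at 5.90-fold (4.19 to 8.54), and the RNA-editing enzyme gene ADAR with 7182 and 24007 reads. Whether the genes of these lists rose as part of the interferon response was not tested, so they are not counted as separate responses.

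Of 21 amino acid stress genes outside the fixed list, 10 were higher and none was lower, with a median of 0.76: FGF21 was 3.72-fold higher (2.76 to 5.11), ADM2 3.27-fold (2.97 to 3.60), INHBE 2.87-fold (2.61 to 3.17) and PCK2 2.31-fold (2.20 to 2.43). Of 19 measured targets of the oxidative stress factor NRF2, 4 were lower, 1 was higher and 14 met the rule in neither direction, with a median of -0.62. HMOX1, heme oxygenase, was 2.15-fold lower, ALDH3A1 was 2.03-fold lower (1.83 to 2.25), and OSGIN1 and TRIM16L were lower too, while SLC7A11, which is shared with the stress response list, was higher. Of 7 aryl hydrocarbon receptor targets, CYP1A1 and ALDH3A1 were lower, 5 met the rule in neither direction and the median was -0.45. Of those 5, TIPARP (1.24-fold, 1.14 to 1.34) and NFE2L2, the gene of NRF2 itself (1.675-fold, 1.55 to 1.81), had folds above 1. The others, CYP1B1, AHRR and NQO1, had folds below 1. ALDH3A1 and NQO1 are also on the NRF2 list, so the 2 medians are not separate observations.

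The interferon pattern was weighed against technical causes. Over all scalings, the thinned library and a pseudocount of 5, the lowest list median was 4.15, far above the random lists, which argues against scaling and depth as the cause. Leukocytes in the lncPSCA culture are argued against as well: 8 leukocyte genes (PTPRC, LCP1, CORO1A, SPI1, CD14, CD68, CD3E and LYZ) together gained 3.99 CPM, or 0.034% of the 11766 CPM gained by the interferon list, with CORO1A the most abundant at 7.30 and 10.5 CPM and PTPRC at 9 and 4 reads. The 132 reads of IFNB1 would follow from a response made by the transfected cells. A response to the lncPSCA RNA and one to the transfected nucleic acid itself (amount, preparation or uptake of plasmid) both predict them. With an empty vector as the only control and 1 library per group, these cannot be told apart. A difference between the 2 cultures unrelated to the insert, such as a batch, stays open because each group has 1 library.

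The second pattern is that PSCA and JRK were both higher. Activation of the whole neighbourhood is argued against, for genes that reached the CPM minimum, by 7 neighbours. Their median log2 ratio was 0.123 and their largest was 1.02, against 3.18 for JRK. Nearby Ly6 genes below that minimum were left out: LY6K had 6 and 18 reads, a ratio of 2.69 (1.02 to 8.29), and LY6D had 2 and 3. LYNX1 had 0 and 1 reads, and SLURP1 and LYPD2 had none. A candidate explanation is that reads of the plasmid transcript were counted on PSCA and, where strand was ignored or the transcript extends into it, on JRK. The 7356 JRK reads would also follow from induction of JRK itself, so without read positions these cannot be told apart, and the sequence of the insert was not given in the sources used here.

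The third pattern is the gradient with transcript length. A difference in RNA fragmentation or size selection between the libraries could produce it, and so could regulation that favours long genes. The Spearman correlation of length with log2 ratio across protein-coding genes was at least 0.255 in each of 4 bins of mean CPM. The gradient was thus present at each level of expression, but both explanations predict this, so it cannot tell them apart. GC content is argued against, since the partial correlation of length was 0.334 at fixed GC content and mean CPM. Regulation that favours long genes was not tested separately, and no RNA quality measure was used here.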
